A study of Mus musculus with 2 samples.

How the data were processed

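Single-cell RNA sequencing was done on mouse (strain C57/Bl6J) neural stem cells grown from the subventricular zone, a neurogenic region along the lateral ventricles. Per the labels' protocols, libraries were made with the 10x Genomics Chromium Single Cell 3′ kit, version 1, which counts unique molecular identifiers (UMIs) near the 3′ ends of transcripts. The labels name 2 libraries, 1 vehicle control and 1 treated with 1 µM of the oxysterol 20HC, both taken 3 days after removal of the growth factors EGF and FGF. Per the submitters' processing notes, the reads were processed with Cell Ranger 2.1.1 against the mm10 build; whether depth was equalised between libraries is not given in the sources used here.

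The deposited counts are whole UMI counts per gene and cell barcode in 1 pooled matrix of 28692 genes and 14685 barcodes. Each barcode ends in the number 1 or 2, and nothing in the labels or files ties a number to a library. No barcode was therefore given a condition, the pooled matrix was treated as 1 sample, and no control against 20HC comparison was made. The 10787 barcodes numbered 1 and the 3898 numbered 2 are called barcode set 1 and barcode set 2, and their values are given side by side with no condition. The label text of the control library also mentions the 20HC treatment; the group was taken from its title.

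Cells with fewer than 500 detected genes (635) or more than 10% mitochondrial UMIs (912) were left out, 1407 barcodes in all. Doublets were called with Scrublet (scanpy 1.11.5) within each barcode set. It marked 291 of 9869 cells in set 1 (2.95%) and 12 of 3409 in set 2 (0.352%), against 7.90% and 2.73% expected from the numbers of cells. The expected shares assume 0.8% per 1000 cells; doublets left among the kept cells were not measured. This left 12975 cells, 9578 of set 1 and 3397 of set 2, with medians of 2818 and 2888 UMIs per cell.

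Counts were scaled to 10000 UMIs per cell and log transformed. The 2000 most variable genes gave 30 principal components, a shared-neighbour graph of 15 neighbours and Leiden clusters at resolution 0.5 (leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15; figures with matplotlib 3.10.9). Clusters were named "X-like" from 14 marker lists. A cluster took the class with the highest mean log2 marker ratio if at least 3 markers had at least 10 UMIs and a CPM at least 2 times that of the other cells and if its 10 leading genes held no more markers of another class than of its own; other clusters stayed unnamed. In this check of leading genes, the genes of the S phase and the G2 and M phase lists also counted as cycling markers. Of the 14 clusters, 11 fell into 8 named classes and 3 stayed unnamed. The lists for committed precursors, myelinating oligodendrocytes, endothelial cells, pericytes, choroid plexus and erythroid cells named no cluster.

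Counts were summed per class and expressed as CPM (UMIs of the gene in parts of 1e+06 UMIs of the class) with exact Poisson 95% intervals; shares of cells carry exact Clopper-Pearson 95% intervals. A count of 0 was taken to allow up to 3 counts. No p-values were computed and no class difference was tested. Log2 ratios between a class and all other kept cells used CPM + 5, and those between barcode sets CPM + 1. A gene with at least 30 UMIs was counted as measured. It was called higher or lower in a class when its CPM differed from that of the other cells by at least 1.5 times, in the same direction in both barcode sets, and the other cells' CPM lay outside the class's Poisson interval. The median ratio of a list was set beside those of 10000 random lists of the same size matched on UMI count, as a description of this matrix.

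The cell filter, clustering settings, marker lists, 15 gene lists and the rule for named genes were fixed before the data were examined. The rule took, per cluster, the 6 genes with the largest CPM ratio (at least 100 UMIs and 25% of cells), every detected gene of the Hedgehog list, the 3 genes with most UMIs of each other list, and, between barcode sets, the 12 largest and 12 smallest ratios over all cells (at least 500 UMIs) and the 5 largest and 5 smallest in each of the 3 biggest classes (at least 200 UMIs). The numeric conditions for naming a cluster, the 30-UMI minimum, the 1.5-fold and interval conditions and the added 5 CPM were set after a first look at the clusters and lists. Genes named outside the rule were chosen after their values were seen. Some items that the rule would name are not reported here.

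Gene positions are from GENCODE M21 (GRCm38, the same assembly as mm10), in which 28339 of the 28692 gene IDs (98.8%) were found. The set comparison was tested on simulated counts of 7322 genes, drawn with counting error only and no variation between cells or libraries. Simulated doublings and halvings were found at median log2 ratios of 0.97 and -0.97, and changes of 1.5-fold at 0.59 and -0.58; the direction was right for 100% of changed genes. None of 7122 unchanged genes (0%) passed 0.5. Simulated cells of 4 classes were clustered with an adjusted Rand index of 0.998. Each simulated class had its own chosen set of strongly raised genes, so the index does not show how securely the real classes were separated. Alternatives tried were other cell filters, doublets kept, other clustering settings, equal UMIs per cell, each barcode set alone, mean CPM over cells, and, between sets, edgeR 4.0.16 TMM scaling (R 4.3.3), other totals, another pseudocount and equal cluster makeup.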

Results

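The deposited matrix holds 41462326 UMIs from 14685 cell barcodes of postnatal mouse neural stem cell cultures taken 3 days after growth factor withdrawal, when such cultures begin to differentiate. The study's title and design ask whether the oxysterol 20HC, a cholesterol derivative, drives oligodendrocyte formation through Gli2, a transcription factor of the Hedgehog pathway. Library labels cover 1 vehicle and 1 20HC library, but barcodes carry only the numbers 1 and 2, so the treatment comparison was not made. What follows compares cell classes within the pooled matrix. Barcode set 1 held 30517055 UMIs (median 2749 per barcode) and set 2 held 10945271 (median 2763.5). There were no replicates, and all intervals are 95% and cover counting error only.

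Which cell classes the cultures held was asked first. Astrocyte-like cells were the largest class, with 6543 of 12975 kept cells (50.4%, interval 49.6 to 51.3%). Cycling-like cells made up 15.8% (2047 cells), progenitor-like cells 9.53% (1236) and fibroblast-like cells 1.66% (216). Cells of the oligodendrocyte precursor-like (OPC-like) class made up 4.31% (559 cells, interval 3.97 to 4.67%) and neuroblast-like cells 3.85% (500 cells). Ependymal-like (71 cells) and microglia-like (36 cells) classes were the smallest.

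The OPC-like cluster was defined by Gpr17, a receptor of differentiating oligodendrocyte precursors, Sox10, a transcription factor of the lineage, Pdgfra, the receptor that marks precursors, and Pllp, Bcas1 and Ccnd1. Dlx6os1, Tubb3, Dcx and Dlx5, genes of young interneurons, led the neuroblast-like cluster, and Egfr, Mfge8, Btg2 and Sox4 were among the genes that led the progenitor-like one. Of the astrocyte-like clusters, 1 was led by Gfap, Cldn10 and Aldoc and another by Pcp4, Gria1 and Agt. The latter, with 3925 cells, had 1 astrocyte marker (Agt), 1 precursor marker (C1ql1) and 1 neuroblast marker (Stmn2) among its 10 leading genes. The naming rule counted each other class apart, so the name of the largest class rests on a narrow margin. The remaining astrocyte-like cluster of 366 cells was shallow (median 1323 UMIs), had a median of 6.71% mitochondrial UMIs, and was led by Vcam1, Entpd2 and the endoplasmic reticulum stress gene Pdia4. The fibroblast-like cluster was led by collagen genes (Col1a1, Col3a1). Its 10 leading genes also held the pericyte or smooth muscle markers Acta2 (4657 against 26.9 CPM) and Vtn.

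The 3 unnamed clusters held 1767 cells (13.6%). One of 865 cells was led by Cenpa, Pttg1 and Cdc20, genes of mitosis, while 11 of 13 neuroblast markers were also raised in it. Its best match was the neuroblast list. It stayed unnamed because its 10 leading genes held 0 neuroblast markers and 1 gene of the G2 and M phase list, Ccnb2. Without the added cell cycle genes the rule would have named it neuroblast-like. A cluster of 326 cells was led by Car9, Adm and Egln3, genes induced by low oxygen. The last (576 cells, median 1086 UMIs) had Lgals1, Fabp7 and Lgals3 among its leading genes. The astrocyte-like share varied widely over the settings: with no cell filter, a cluster of 4612 cells with 5 raised astrocyte markers stayed unnamed and the share was 0%, and with each barcode set clustered alone it was 21.6%. Neuroblast-like shares ran from 0% to 16.4% over the settings, progenitor-like shares from 0% to 12.5% and OPC-like shares from 3.03% to 5.44%. Barcode set 2 clustered alone had no cluster named OPC-like, progenitor-like or ependymal-like. No cell kept the progenitor-like name at resolution 0.3, with 15 components, without cell cycle genes or without list genes in clustering, so that class is the least secure.

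**Figure D1:**
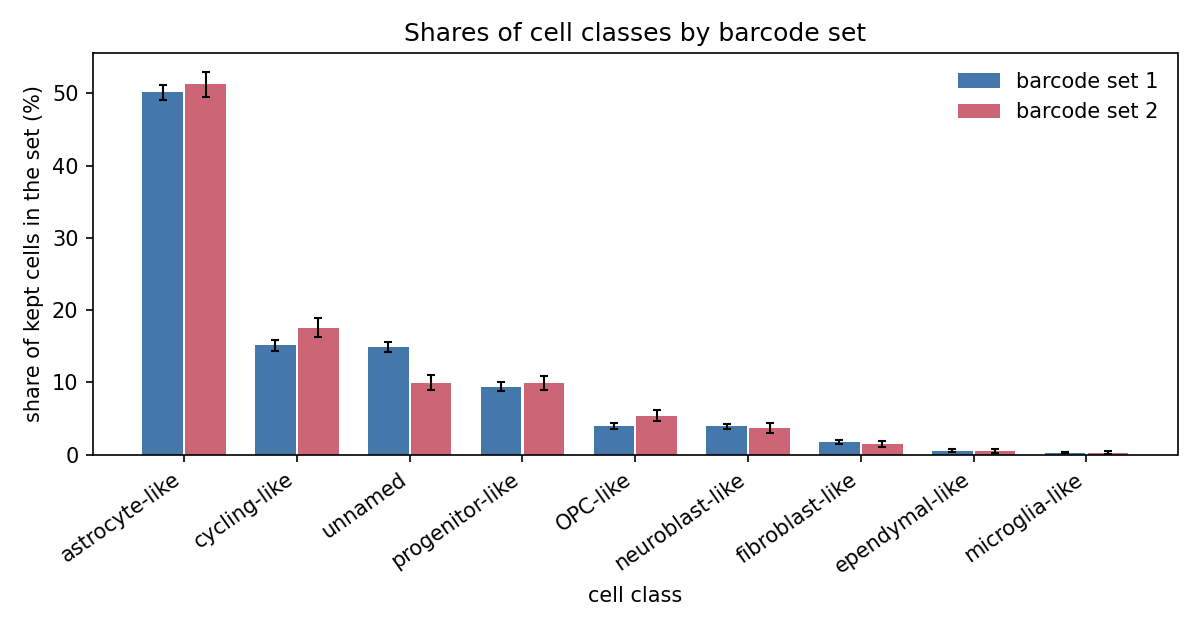
Share of kept cells (y axis, %) in each cell class (x axis) for barcode set 1 (blue, 9578 cells) and barcode set 2 (red, 3397 cells); bars start at 0 and error bars are exact binomial 95% intervals. OPC-like cells made up 3.94% of set 1 and 5.36% of set 2, and unnamed clusters 14.9% and 9.98%; the sets carry no condition.

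Hedgehog pathway genes were compared between classes because the study's question concerns Gli2. Gli2 UMIs were found in 0 of 559 OPC-like cells, which allows a share of cells with a UMI of up to 0.537%. In astrocyte-like cells they were found in 107 of 6543 (1.64%, interval 1.34 to 1.97%). Median depths were 3244 UMIs in OPC-like and 3004 in astrocyte-like cells. At such depths a cell that expresses a low gene can yield no UMI, so these are not shares of cells that express Gli2. Summed over the class, Gli2 was at least 3.11-fold lower in OPC-like cells than in all others, taking 3 UMIs over the class (1.58 CPM) as the limit and 4.92 CPM in the other cells. Gli3, the related repressor-forming factor, was at 2.11 CPM against 9.58 CPM, and Smo, the pathway's transducer, at 16.9 against 26.1 CPM. Ccnd1, a G1 cyclin and a Hedgehog target among other inputs, went the other way, at 849 CPM (808 to 891) against 73.9 CPM, and is 1 of the genes that define the cluster. Gli1 and Ptch1, the usual readouts of pathway activity, were near the floor or alike: Gli1 was seen in 10 of 12975 cells, and Ptch1 stood at 11.1 CPM in OPC-like cells (6.85 to 16.9) against 13.1.

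Over the 16 measured genes of the list, 1 was higher in OPC-like cells (Ccnd1), 8 were lower (Gli2, Gli3, Smo, Boc, Cdon, Gas1, Mycn and Ccnd2), and 7 were neither. The median log2 ratio was -0.47 (-0.48 in barcode set 1 and -0.66 in set 2), at the 0.64th percentile of random lists. That percentile was taken for the comparison with all other cells only. The list mixes pathway components, the repressor-forming Gli3 among them, with targets, so its median does not measure pathway activity. Hhip (5 UMIs) and Shh (1) were not measurable at this depth. Astrocyte-like cells made up 50.4% of cells and had the highest Smo level, so OPC-like cells were also compared with the other cells that were not astrocyte-like. There the median was -0.26, and Gli2, Gli3, Cdon, Gas1, Mycn and Ccnd2 were still lower, while Smo and Boc were not. Without cells that had a UMI of 5 mitotic genes the median was -0.73, and with thinned cells -0.69.

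In astrocyte-like cells, 7 of the 16 genes were higher (Smo, Dhh, Boc, Evc, Evc2, Gpr161 and Kif7) and 4 lower (Cdon, Mycn, Ccnd1 and Ccnd2). Smo reached 35.9 CPM (33.3 to 38.6) against 14.3 in the other cells, and the co-receptor gene Boc 7.07 against 2.33 CPM. Ccnd2, a cyclin of dividing progenitors, was at 305 CPM in astrocyte-like, 4449 in cycling-like and 9694 in neuroblast-like cells. The co-receptor gene Cdon was higher in cycling-like cells (18.2 CPM against 5.29). In progenitor-like cells, a class that was absent in 4 of the clustering settings, Gas1, Mycn and Ccnd1 were higher and Boc lower. Sufu was called in fibroblast-like cells alone among the 6 classes of more than 200 cells, at 19.1 against 8.96 CPM.

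**Figure D2:**
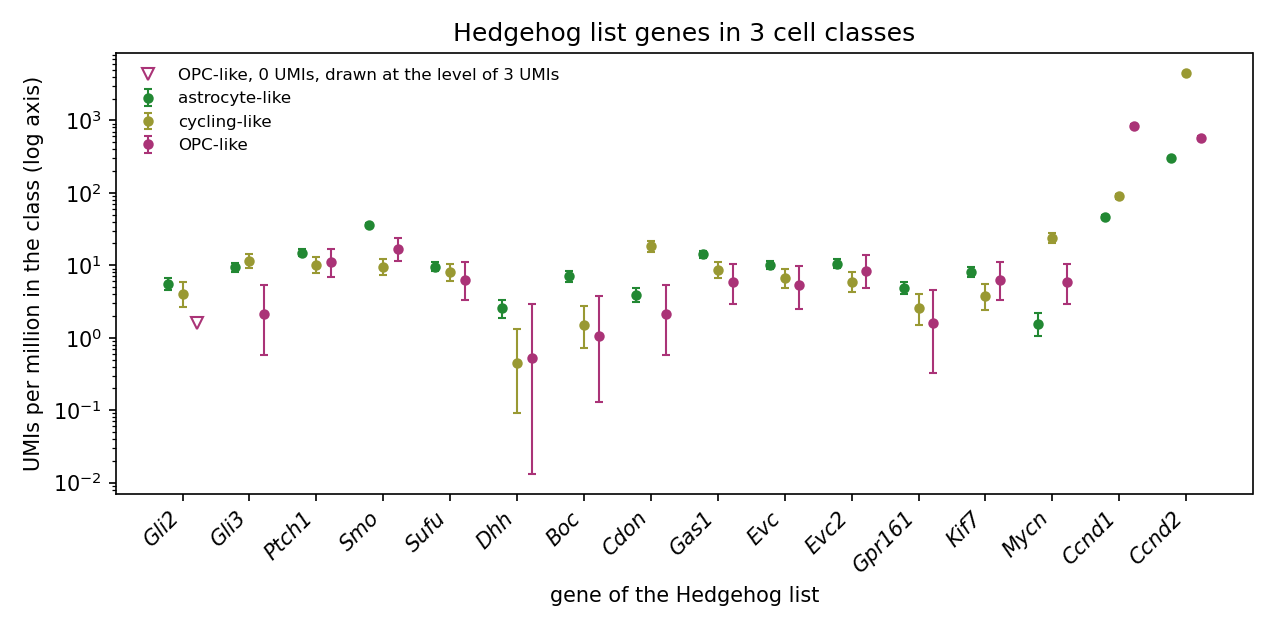
CPM (y axis, log scale) of the 16 measured Hedgehog list genes (x axis) in astrocyte-like (green), cycling-like (olive) and OPC-like (purple) cells; points are class sums and bars exact Poisson 95% intervals. Gli2 had 0 UMIs in OPC-like cells and is drawn as an open triangle at 1.58, the level of 3 UMIs, while Ccnd1 stood at 849 there.

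The state of the OPC-like cells was asked next. Pdgfra UMIs were seen in 25.2% of them (21.7 to 29.0%; median 3244 UMIs) against 1.03% of cycling-like cells (median 3179 UMIs), and Gpr17 UMIs in 140 of the 559 cells (21.5 to 28.9%) against 0.195%. Both genes were seen in 7.51% of the cells. UMIs of at least 1 of Mki67, Top2a, Cdk1, Ube2c and Cenpf, genes of dividing cells, were present in 63.9% of OPC-like cells (59.7 to 67.9%; median 3244 UMIs), 91.3% of cycling-like (3179 UMIs), 64.4% of neuroblast-like (2260.5 UMIs) and 45.8% of fibroblast-like cells (4190.5 UMIs). In astrocyte-like cells (3004 UMIs) the share was 14.4%; free RNA and dividing cells were not told apart there. Depth differed between these classes, so the shares are not directly comparable. The G2 and M phase list was higher for 12 of 14 genes in OPC-like cells, with Ube2c at 516 CPM against 289, and a median log2 ratio of 0.80; Top2a was not called, at 388 against 283 CPM. Against other cells that were not astrocyte-like, 0 of the 14 genes were higher, 2 were lower and the median was -0.29, so the higher level held only against comparison cells that included the astrocyte-like class.

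Among 11 measured transcription factors of the oligodendrocyte lineage, 6 were higher in OPC-like cells (Olig1, Olig2, Sox10, Sox8, Nkx2-2 and Sox4) and 2 lower (Nkx6-2 and Sox11). Of these 11 genes, 3 were also markers used to name the class. Sox4 stood at 557 CPM against 364, a ratio that changed sign without astrocyte-like comparison cells, and Sox11, which marks young neurons, at 192 against 355. Myrf, the factor that starts myelin gene expression, was seen in 12 OPC-like cells (2.15%) and 1 astrocyte-like cell.

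Of 9 measured myelin genes, 8 were higher in OPC-like cells, with Cnp at 592 CPM (557 to 627) against 160 and Mbp at 98.6 against 16.0. The list's median was 0.75 in barcode set 1 and 2.58 in set 2. A few cells held much of the signal in set 2 alone: the 5 cells with most myelin UMIs held 49.8% of them, against 8.14% in set 1, and 1 cell alone had 375, against a median of 2 per cell. Without the 5 such cells of each set, chosen after the values were seen, 5 of the 9 genes met the fold and interval conditions over the pooled cells (among them Mbp, Cnp and Cldn11). The list's median log2 ratio then went from 1.85 to 0.62, and some fall follows from leaving out cells by UMIs of this same list.

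Sterol-related genes were compared because the study's compound is an oxysterol, a class of molecules that activates the nuclear receptor LXR and lowers cholesterol synthesis. Astrocyte-like cells had 8 of 11 measured LXR targets higher and 2 lower (Mylip and Apod), with a median log2 ratio of 1.45. Apoe, which carries lipid between brain cells, stood at 7982 CPM (7943 to 8021) against 2091, Smpdl3a at 144 against 43.7, and Pltp at 109 against 36.5. Srebf1, the regulator of fatty acid synthesis, was at 106 against 29.6 CPM. In cycling-like cells 10 of the 11 genes were lower, and in OPC-like cells 7 were lower and none higher. Without astrocyte-like comparison cells 4 of these 7 stayed lower (Apoe, Smpdl3a, Pltp and Abca1), and Srebf1, Lpcat3 and Scd1 were not called. Apod was newly lower there (13.7 against 33.3 CPM), but fibroblast-like cells held 508 of its 614 UMIs. Its level in OPC-like cells was above those in astrocyte-like (2.54 CPM) and cycling-like cells (1.34 CPM). Mylip, with 0 UMIs in OPC-like cells, was also called lower. The level of 3 UMIs (1.58 CPM) is less than 1.5-fold below its 1.98 CPM in the comparison cells, so a lower level was not shown. Apoe UMIs were still found in 84.1% of OPC-like cells (median 3244 UMIs) and 65.6% of neuroblast-like cells (median 2260.5 UMIs); free RNA and low expression were not told apart. In barcode set 1 the LXR median in astrocyte-like cells was 1.34 and in set 2 it was 1.63.

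Fatty acid synthesis genes followed the LXR targets, with 7 of 10 higher and 1 lower (Elovl6) in astrocyte-like cells and a median log2 ratio of 1.12; Scd1 is in both lists. Scd2, a desaturase, was at 1270 CPM against 305, Fads1 at 221 against 58.2, and Elovl5 at 111 against 48.8.

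Cholesterol synthesis genes were split between classes. In OPC-like cells 8 of 23 measured genes were higher and 0 lower (Sqle, Idi1, Fdps, Lss, Cyp51, Mvd, Mvk and Acat2), with Fdps at 170 CPM (152 to 189) against 75.8 and Acat2 at 102 against 51.4. The median log2 ratio was 0.36, above all but 0.01% of random lists, with 0.44 in barcode set 1 and 0.21 in set 2. Without astrocyte-like comparison cells 13 of the 23 genes were higher and 0 lower; Fdps stayed higher (88.6 CPM in those cells), but Acat2 was not called (102 against 73.5 CPM). In astrocyte-like cells 8 genes were higher, among them Hmgcs1 (131 against 47.2 CPM), the first committed step of the pathway, and 2 were lower (Acat2 and Ebp). In cycling-like cells 11 were lower and 2 higher.

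**Figure D3:**
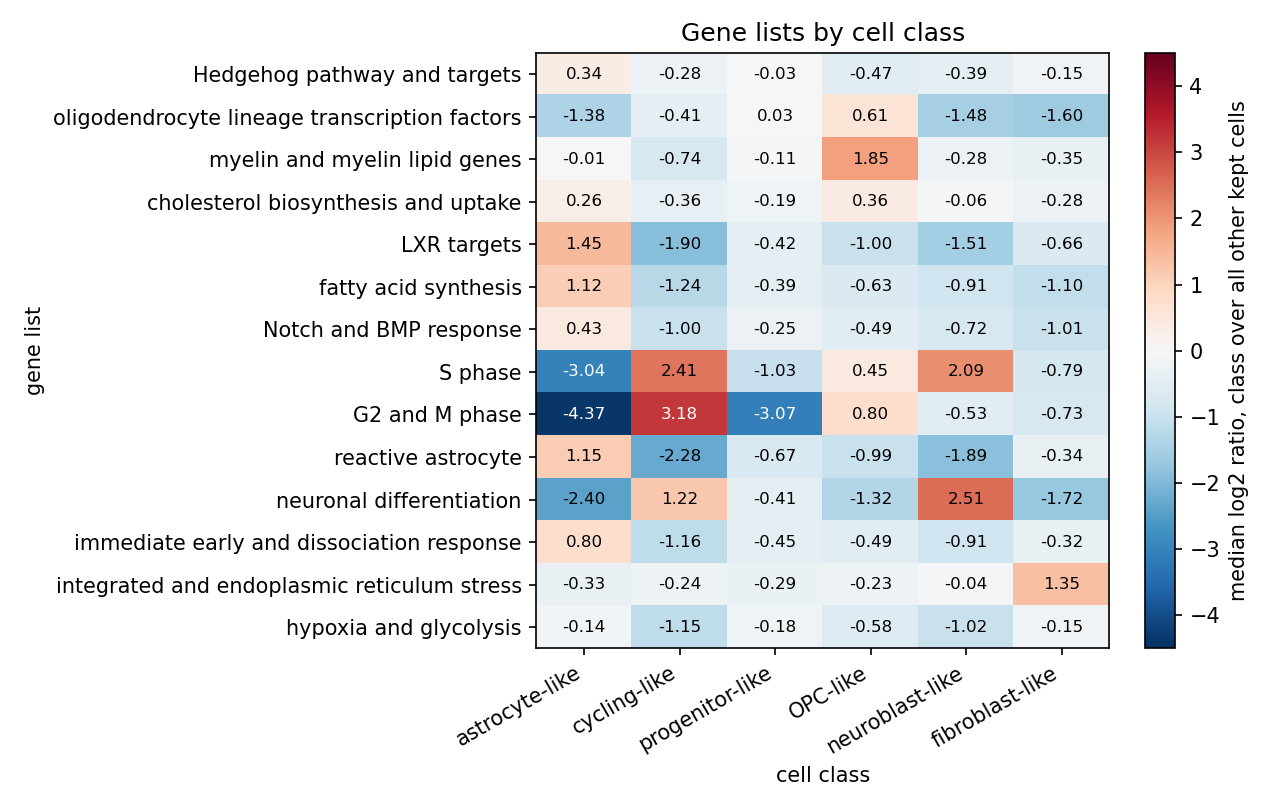
Median log2 ratio of each gene list (rows) in a cell class over all other kept cells, for the 6 named classes with more than 200 cells (columns); red is higher, blue lower, and the value is printed in each cell. LXR targets stood at 1.45 in astrocyte-like and -1.90 in cycling-like cells, and the myelin list at 1.85 in OPC-like cells.

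Of 10 measured reactive astrocyte genes, 9 were higher in astrocyte-like cells (Gfap 5277 against 1010 CPM, Vim 4202 against 1897, Cd44 179 against 52.6), and Gfap is also a marker of the class. Vim is also a marker of the neural stem or progenitor list, so the list does not show a reactive state by itself. The Id genes of the Notch and BMP list were higher in astrocyte-like cells, with Id3 at 686 against 145 CPM, in a list of 6 higher and 4 lower of 12. Neuroblast-like cells had all 14 S phase genes higher (Rrm2 920 against 206 CPM), while 7 of 14 G2 and M phase genes were lower (Cenpf 69.2 against 244 CPM) and none higher. The comparison cells held the unnamed mitotic cluster of 865 cells, in which 11 of 13 neuroblast markers were raised. Only a G2 and M phase gene among its leading genes kept that cluster out of the neuroblast-like class. In both phase lists 13 of 14 genes entered the clustering, so this contrast is not independent of how the clusters were drawn. With called doublets kept, when the neuroblast-like class held another cluster, its Cenpf and Ube2c ratios changed sign. Of 14 neuronal genes, 13 were higher in cycling-like cells too, with Tubb3 at 680 against 221 CPM; Stmn2 was lower there and higher in astrocyte-like cells (276 against 96.6 CPM).

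Some of the lists' genes entered the clustering, 3 of the 20 genes of the Hedgehog list, 6 of 11 LXR targets and 2 of 24 cholesterol genes among them. Nearly all genes of the S phase, G2 and M phase and neuronal lists entered it (13 of 14 in each). So did 9 of 12 reactive astrocyte genes, 9 of 13 lineage transcription factors, 7 of 10 hypoxia and glycolysis genes and 6 of 13 myelin genes. Class differences in the lists are therefore not independent of how the classes were drawn. With the genes of all lists left out of clustering, the Hedgehog and cholesterol medians in OPC-like cells were -0.48 and 0.43, the LXR median in astrocyte-like cells 1.23 and the myelin median in OPC-like cells 0.72.

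Positions of the leading genes on GRCm38 are as follows. Gli2 (ENSMUSG00000048402) lies on chromosome 1 from 118834132 to 119053619 and Ccnd1 (ENSMUSG00000070348) on chromosome 7 from 144929931 to 144939925, both on the minus strand. Apoe (ENSMUSG00000002985) lies on the minus strand of chromosome 7 from 19696109 to 19699188. Each is annotated as protein coding, and values are UMIs counted near the 3′ ends of transcripts and summed per gene.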

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

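Clustering each set alone, leaving out unnamed clusters, astrocyte-like comparison cells, mitotic cells, gene lists or the cells richest in myelin UMIs, dropping shallow clusters and removing the GC trend were chosen after the data were seen; the others were planned. No control against 20HC alternative was run, as barcodes carry no condition. Over the main results 65 alternative values stayed within counting error or 1.5-fold of the count, 52 moved and 2 changed sign; over single genes and small classes 936 stayed, 362 moved and 11 changed sign. No paired analysis was possible because barcodes carry no sample, there is 1 library per condition and the results come from no test. Causes of the moves were not tested unless given.

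With no cell filter, shares were 0% astrocyte-like, 12.3% cycling-like, 3.85% OPC-like and 1.34% neuroblast-like. With at least 1000 genes and at most 5% mitochondrial UMIs, astrocyte-like cells made up 52.5%, OPC-like 5.19% and neuroblast-like 4.29%. With doublets kept, astrocyte-like cells made up 52.6% and neuroblast-like 5.88%. With called doublets kept, the class held another cluster; the Ptch1 log2 ratio in neuroblast-like cells was 0.0912, the Ube2c log2 ratio in neuroblast-like cells 0.0905 and the Cenpf log2 ratio in neuroblast-like cells 0.16, each of changed sign. At resolution 0.3 the neuroblast-like share was 0%, its cells lying in an unnamed cluster of 1550; at resolution 1 shares were 44.5% astrocyte-like, 17.5% cycling-like and 10.1% neuroblast-like. With 2 times as many variable genes these were 52.5%, 16.6% and 3.48%, and with 15 components 36.3%, 16.8% and 14.3%, with 5.44% OPC-like. Without cell cycle genes, cycling-like cells made up 16.7% and neuroblast-like 2.19%. With cells thinned to 1400 UMIs, and 897 shallower cells of set 1 and 209 of set 2 left out, so that depth and cells both changed, shares were 55.5% astrocyte-like, 17.5% cycling-like and 5.30% OPC-like. With each set clustered alone they were 21.6%, 14.1% and 3.03%, and with gene lists left out of clustering 48.7% astrocyte-like, 14.9% cycling-like and 16.4% neuroblast-like. The progenitor-like share was 0% at resolution 0.3, with 15 components, without cell cycle genes and without list genes. Elsewhere it ran from 4.62% to 12.5%, where 4.62% pooled the sets clustered alone (6.25% in set 1 and 0% in set 2).

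Hedgehog medians in OPC-like cells were -0.69 with thinned cells and -0.73 without mitotic cells. LXR medians in astrocyte-like cells were 1.34 in set 1, 1.63 in set 2 and 1.23 without list genes in clustering. Cholesterol in OPC-like cells was 0.21 in set 2. Myelin in OPC-like cells was 1.95 thinned, 0.75 in set 1, 2.58 in set 2, 0.72 without list genes in clustering, 0.62 without the cells richest in myelin UMIs and 2.50 without mitotic cells. G2 and M phase in OPC-like cells was 0.63 thinned, 0.90 without unnamed clusters, 0.85 without list genes, and -2.86 without mitotic cells, which follows from leaving out cells by 5 of its genes. Fatty acid synthesis in astrocyte-like cells was 1.26 in set 2 and 1.26 without unnamed clusters. Between sets, a pseudocount of 5 CPM left 7 genes at or above 0.5 in place of 13. Genes with under 30 UMIs, Gli1 among them, were too shallow to compare.

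With astrocyte-like cells left out of the comparison cells, medians in OPC-like cells were -0.26 for Hedgehog, 0.64 for cholesterol and 2.103 for myelin, and -0.29 for G2 and M phase, of changed sign; 13 cholesterol genes were then higher in place of 8, and 0 G2 and M phase genes in place of 12. There the Smo log2 ratio in OPC-like cells was 0.203, the Sox4 log2 ratio in OPC-like cells -0.122, the Scd2 log2 ratio in OPC-like cells 0.136, the Fads1 log2 ratio in OPC-like cells 0.0879, the Ube2c log2 ratio in OPC-like cells -0.300, the Cenpf log2 ratio in OPC-like cells -0.369, the Fos log2 ratio in OPC-like cells 0.427 and the Junb log2 ratio in OPC-like cells 0.0375, each of changed sign.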

Other observations

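The tests of GC content, cluster makeup, depth and mitochondrial share were set before their results were seen, although the patterns were found in these data. Barcode sets have no condition, so no biological explanation such as the treatment was tested for any pattern between them.

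Stress and hypoxia lists differed between classes beyond those described so far. In fibroblast-like cells 8 of 10 genes of the integrated and endoplasmic reticulum stress list were higher, with the chaperone gene Hspa5 at 711 CPM (658 to 767) against 261 and Atf5 at 143 against 49.8; astrocyte-like cells had 5 lower and none higher. Immediate early genes, which can respond to cell dissociation, were higher for 8 of 11 in astrocyte-like cells (Fos 249 against 85.0 CPM, Junb 127 against 31.8) and lower for 9 in cycling-like cells. Dusp1 was called the other way in both, lower in astrocyte-like (1.10 against 5.05 CPM) and higher in cycling-like cells (5.22 against 2.48 CPM). Of 10 hypoxia and glycolysis genes, 8 were lower in cycling-like cells (Egln3 9.10 against 41.8 CPM), while Ldha was not called, at 341 against 481. Xist and the Y-linked Ddx3y were both present in both sets (Xist 991 and 1132 CPM, Ddx3y 16.0 and 19.2 CPM), so each set held cells of both sexes.

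Between barcode sets, over all kept cells and 7208 genes, 13 had a log2 ratio (set 2 over set 1) of at least 0.5 and 142 of at most -0.5. Highest were Sez6, Cdk6, Srebf1 (60.4 and 96.0 CPM in sets 1 and 2), Sorcs2, Lrr1, Cks1brt, Gabrb1, Mpp6, Olig1 (38.3 and 56.3), Ntn1, Abca1 (63.8 and 93.1) and Shroom3. Lowest were Gm10260, H2afj, Gm1673, Syap1, 0610010K14Rik, Rpl35 (317 and 145 CPM), AY036118, Emc6, mt-Nd4l, Oxld1, Gm10076 and Tpgs1; Gm10260 and Gm10076 are predicted genes, and reads shared with near copies were not ruled out. Apoe stood at 5985 CPM in set 1 and 3022 in set 2, against its list: 8 of 11 LXR targets lay above 0 and 3 below (median 0.14, and 0.28 with the same cluster makeup). Of 23 cholesterol genes 20 lay below 0 (median -0.23), and of 14 G2 and M phase genes all 14 lay above 0 (median 0.18). Cycling-like cells made up 17.6% of set 2 and 15.1% of set 1; with both sets weighted to the same cluster makeup 7 of the 14 lay above 0 and the median was -0.01, while the cholesterol median stayed at -0.26. Ptch1 stood at 11.0 and 18.5 CPM and Gli2 at 4.33 and 5.60 CPM.

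In the 3 biggest classes, the largest ratios were those of Tagln and Bcl2 in astrocyte-like cells (19.8 and 48.6 CPM for Tagln), Gm12355 and Sez6 in cycling-like cells, and Cat and Ntsr2 in progenitor-like cells (64.0 and 116 CPM for Cat). The smallest were those of Gm10260 in astrocyte-like cells, Fbxo2 in cycling-like cells (55.4 and 13.3 CPM) and Gm1673 in progenitor-like cells. The astrocyte marker Aldoc was also among the 5 smallest in cycling-like cells (95.1 and 32.8 CPM). Gfap was alike in astrocyte-like cells (5296 and 5226 CPM) but not in cycling-like (493 and 231) or OPC-like cells (734 and 236). In microglia-like cells Gfap went the other way (655 and 869 CPM). Free RNA, doublets and expression were not told apart there. No sign of which set was treated was taken from any of these values.

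The 142 lower genes in set 2 were weighed against technical causes. The trend over bins of GC content at the 3′ end was nearly flat, with bin medians from 0.01 to 0.07 in log2, too small for a general trend to give ratios of -0.5. That 100% of the genes stayed at or below -0.5 once the trend was removed follows from bin medians that were all above 0 and adds nothing to this. The 142 genes had a median GC content of 47.6%, against 44% over all genes compared. Bin medians over all genes cannot show a GC-linked loss limited to a small subset, so such a loss stays open. Different makeup of cell clusters accounts for few, since 88.7% stayed with both sets weighted to the same makeup, and 134 of the 142 were lower in set 2 in each of the 3 biggest classes. Differences between the libraries in preparation, sequencing, free RNA or remaining doublets, and the treatment itself, stay open and were not tested.

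The unnamed shallow cluster made up 5.55% of set 1 and 1.30% of set 2. Damaged cells rich in mitochondrial RNA would need a raised mitochondrial share, and its median was 0.334 times that of the other cells (1.03% against 3.09%), which argues against them. Whether low depth alone made the cluster cannot be told apart from a distinct state: with cells thinned to 800 UMIs and shallower ones left out (541 of the cluster's 576 cells stayed), 79.9% of those 541 lay in a new cluster of which they were the majority, just under the 80% that was set as the bound against depth. Loss of cytoplasm with loss of mitochondria was not tested.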
